A study of Homo sapiens with 6 samples.

How the data were processed

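ATAC-seq, which uses a transposase to cut and tag open chromatin, was run on 22Rv1 cells, an established human prostate cancer cell line. The libraries carry the labels FOXA1_dTAG at 0 h, 1 h and 24 h, with 2 libraries per time point and 6 in all. FOXA1 is a forkhead pioneer transcription factor of luminal prostate cells, and a dTAG is a fusion tag through which a small molecule directs a protein to degradation. The labels name neither the molecule nor its dose. They also do not say whether the replicates came from separate cultures, so the spread between replicates may be technical.

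One list of peaks per library was used; replicates were not pooled. Per the submitters' processing notes, FastQC, fastp, Bowtie2 and MACS2 were used with the genome build hg19, without versions or parameters. Whether reads were shifted for the transposase cut or duplicates removed is not given in the sources used here. The fold (a ratio of the pileup at the summit to the local background), the −log10 p and the −log10 q of each peak are the authors' deposited values from MACS2. The deposited score is 10 times the −log10 q cut to a whole number. The lowest −log10 q was between 1.30 and 1.32 in every list, which corresponds to a q threshold of 0.05. Coordinates are given in hg19.

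No read counts were used here, but the deposited fold and −log10 p together give back a pileup. Assuming MACS2's usual formulas (a pseudocount of 1 and a Poisson p), a whole-number pileup matched the deposited −log10 p within 0.001 for 100.0% of peaks in each list. The most frequent background pileup divided by the shortest peak, which MACS2 sets to its estimated fragment length, gave a relative depth in tags per kb. It was 10.4 and 8.24 at 0 h, 8.14 and 8.62 at 1 h, and 7.33 and 7.04 at 24 h. The shortest peak was 155 and 111 bp at 0 h, 172 and 160 bp at 1 h, and 147 and 136 bp at 24 h. A deeper library finds weaker peaks, and a shorter fragment gives narrower peaks, so both can move the length of a list. Folds were used only to describe and rank peaks within their own list.

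Peaks on the 22 autosomes and X were merged across the 6 lists wherever they overlapped by at least 1 bp, which gave 167726 regions. Peaks on Y and the mitochondrial genome entered only an alternative. A region was called lost when both earlier libraries held a peak and neither later library did, and gained in the reverse case. It was called strong in a library that held a peak with −log10 q of at least 10, and a strong lost region was strong in both earlier libraries and had no peak of any strength in either later one. That stricter definition was listed as an alternative before the data were examined. Its use as a result beside the first was decided afterwards, and so were the single pairs of libraries, the state of lost regions at the third time, the widths, strengths, chromosomes and 1 Mb windows. Each count was set beside the 4 counts given by the other 2 ways to split the same 4 libraries. Each side of these splits holds 1 library of each time. A difference in depth or list length between times is thus largely balanced in them. They do not show what depth alone would give. Each count was also set beside 100 draws that kept each region's number of libraries with a peak and, on average, each library's number of regions. With 2 libraries per time point, the exact two-sided permutation test used between 2 times cannot go below a p of 0.333. Tested on simulated lists for 24 h against 0 h (167726 regions), observed over drawn counts were 1.02 for lost and 1.00 for gained regions when none was changed. These lists were simulated from a level per region and an effect per library, as the draws assume. They check the calculation and not how well the draws describe real lists. With 2000 regions made lost, all of them were called (100.0%), which the definition fixes. They had been picked from regions in both 0 h libraries and removed from both 24 h libraries. The observed count of 7236 was only 1.17 times the drawn 6207, so the draws absorb part of a real change.

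Strength was the mean over the libraries holding a region of the within-list percentile of its highest fold. The rule for named regions, fixed before the data were examined, takes for each comparison and direction the 5 regions with the highest strength. Forkhead and other motifs, promoter shares, gene lists and gene names had been planned too, and so had lists of markers of other cell types. They need the hg19 sequence or annotation, which was not used here, so none of them was run. A table of protein-coding genes on GRCh38.p14 served only to count genes per chromosome; no position was taken from it. The time points share replicate numbers, and the labels do not say what a number stands for, so libraries were not paired in the comparisons reported first.

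The alternatives set before the data were examined were a −log10 q of at least 5, strong peaks against no peak, every list shortened to the length of the shortest (101755 peaks) by −log10 p, 500 bp windows on summits, a library counted as present only where its peaks cover 50% of a region, all chromosomes, and leaving out each library in turn. Others were chosen after seeing the data. The peaks per library were also compared within replicate numbers, the overlaps were set against lists with a different 0 h library for each comparison, and the summit windows and the omission of each library were extended to strong counts. Strong peaks were also defined by a −log10 q of at least 5, 15 or 20, and all lists were limited to a −log10 q of at least 10. Presence among the 20000, 30000, 40000 or 60000 top-ranked peaks of each list was set against absence from lists of one length; the 40000 used in the text was taken after the counts at all 4 ranks had been seen. Calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.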

Results

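Open chromatin was profiled in 22Rv1 prostate cancer cells carrying a degradation tag on FOXA1, at 0 h, 1 h and 24 h, with 2 libraries per time point. The series addresses how pioneer factors shape chromatin entry of cohesin and genome folding, and these libraries ask which open regions depend on FOXA1 early and late after its degradation is triggered. The degradation itself is not measured in the files used here. On the autosomes and X, the lists held 118259 and 125396 peaks at 0 h, 110661 and 117942 at 1 h, and 101755 and 114362 at 24 h. The mean fell from 121828 ± 5047 (SD, n = 2) at 0 h to 114302 ± 5148 at 1 h and 108058 ± 8914 at 24 h, but the exact two-sided permutation p between 0 h and either later time was 0.333, the smallest that 2 against 2 libraries can give, and between 1 h and 24 h it was 0.667. Peaks covered 53.7 ± 6.71 Mb at 0 h, 56.8 ± 1.28 Mb at 1 h and 47.3 ± 1.82 Mb at 24 h (SD, n = 2). The mean relative depth, recovered from the background of each list, was highest at 0 h (9.34 ± 1.56 tags per kb), lower at 1 h (8.38 ± 0.339) and lowest at 24 h (7.19 ± 0.20), so mean depth and time move together. Single libraries of 0 h and 1 h overlapped in depth, since 0h replicate 2 had 8.24 and the 1 h libraries 8.14 and 8.62.

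Of the 99494 regions held by both 0 h libraries, 72695 (73.1%) had a peak in all 6 libraries. A 0 h library shared 85.0% ± 1.23 of its regions with the other 0 h library, 79.9% ± 1.29 with a 1 h library and 73.3% ± 0.979 with a 24 h library (SD over the 2 libraries). In the reverse direction the 24 h libraries differed. One shared 88.9% of its regions with the other and 84.9% and 84.97% with the 0 h libraries, and the other 79.0% with its replicate and 80.1% and 80.3% with the 0 h libraries; such shares also depend on the length of the other list. The base-pair Jaccard index, the shared length over the joint length, averaged 0.663 within 0 h, 0.694 within 1 h and 0.674 within 24 h. It was 0.650 between 0 h and 1 h, 0.639 between 1 h and 24 h, and 0.603 between 0 h and 24 h. The mean for 0 h and 1 h hides a difference between the 0 h libraries. With the 1 h libraries, 0h replicate 1 had 0.673 and 0.672, above its 0.663 with its own replicate. The values of 0h replicate 2 were 0.621 and 0.632. Of the 15 ways to pair the 6 libraries, the pairing by time gave the highest excess of similarity within pairs (0.0468, against 0.0248 for the next), an exact one-sided permutation p of 0.0667 and the smallest this design allows. No 2 lists were copies of each other, with at most 25 identical intervals between any pair.

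One hour after the start, 815 strong 0 h regions had no peak in either 1 h library, while 17 strong 1 h regions had none in either 0 h library. The gains depended on the definition, with 88 (and 936 losses) in 500 bp summit windows and 694 (and 3210 losses) with a −log10 q of at least 5. The 815 were 1.51% of the 54131 regions strong in both 0 h libraries. The other splits of the same 4 libraries, which mix the times on each side, gave 1 to 4 such regions. Over all peaks as deposited, 7438 regions were lost and 3704 gained, against 1924 to 2682 in the other splits, and 83375 regions had a peak in all 4 libraries. Draws that kept each library's number of regions gave 4462 ± 61 lost and 2405 ± 48 gained regions (SD over 100 draws), so observed counts were 1.67 and 1.54 times the drawn ones. In single pairs of libraries, 3.08% to 4.15% of the strong regions of a 0 h library lacked a peak in a 1 h library, compared with 0.173% to 0.741% between replicates of one time and 0.459% to 0.856% from 1 h to 0 h.

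The strongest regions lost at 1 h lay on chromosomes 18, X, 13 and 3. The first, 18:71374227-71374729, had folds of 17.9 and 18.1 over background at 0 h. X:91476319-91477074 had 16.97 and 16.8, 13:97577991-97578559 had 16.9 and 16.4, 3:75003610-75003965 had 16.2 and 16.03, and 18:28949321-28949822 had 16.5 and 15.7. All 5 also lacked a peak in both 24 h libraries. The strongest regions gained at 1 h were weaker within their lists, with mean percentiles of 71.2 to 80.6 against 97.6 to 99.2 for the lost ones. Of these, 13:88576020-88576340 had folds of 9.58 and 10.1, and 2:151764876-151765503 had 9.17 and 10.5. The others were 14:43010692-43011349, 3:106019100-106019454 and 18:40639958-40640362, with mean folds of 9.64, 8.78 and 8.37, and all 5 kept a peak in both 24 h libraries. The excess of lost over gained regions among all peaks depended on the overlap rule. Where peaks had to cover 50% of a region, 7154 were lost and 6900 gained. Without 1h replicate 1, gains (12623) outnumbered losses (11235). A gain then needed a peak in 1 library and a loss still in 2, and without a 0 h library the reverse held. Such counts therefore do not show that the direction rests on a single library. The losses and gains were 18120 and 7521 without 0h replicate 1, 15698 and 7108 without 0h replicate 2, and 12322 and 10835 without 1h replicate 2. Without 0h replicate 2 or 1h replicate 2, the strong lost regions rose to 1678 and 1307, since fewer libraries had to meet the condition, and strong gained regions numbered 71 to 177 without any 1 of the 4 libraries.

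**Figure D1:**
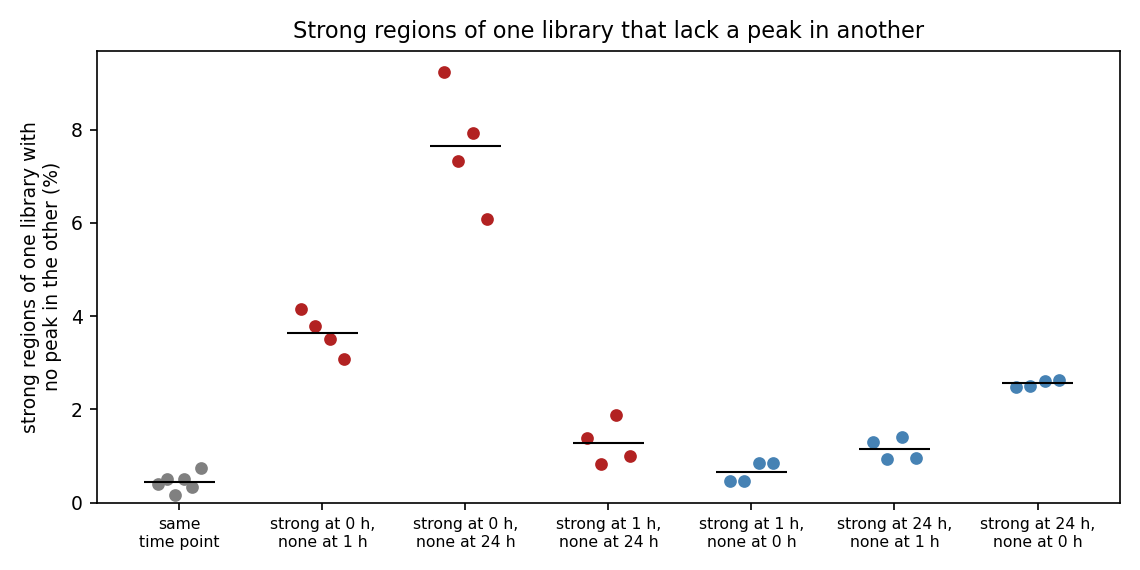
Each point is an ordered pair of libraries: the y axis gives the percent of strong regions (−log10 q of at least 10) of the first library that have no peak in the second; black lines are means, grey points are replicates of one time, red points go from an earlier to a later time and blue points from a later to an earlier one. From 0 h to 24 h the values lie between 6.09% and 9.24%, above the 0.173% to 0.741% between replicates.

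At 24 h, 2177 strong 0 h regions, 4.02% of the total, had no peak in either library, and 343 strong 24 h regions had none at 0 h. The other splits of these 4 libraries gave 1 to 8, but they mix the times on each side and do not show what the lower depth at 24 h would give. Over all peaks, 13019 regions were lost, 13.1% of the 99494 held by both 0 h libraries, and 5696 were gained, against 1237 to 2634 in the other splits; 75341 regions had a peak in all 4. The draws with fixed library totals gave 7338 ± 71 lost and 2180 ± 40 gained regions, so observed counts were 1.77 and 2.61 times the drawn ones. Of the strong regions of a single 0 h library, 6.09% to 9.24% lacked a peak in a 24 h library, and 2.49% to 2.63% of those of a 24 h library lacked one at 0 h. With lists of one length and presence among the 40000 top-ranked peaks, 781 regions were lost and 167 gained, and the other splits gave 0. The ratio of losses to gains depended on the rank, from 101 losses and 1 gain among the top 20000 to 2236 and 1039 (2.15 times) among the top 60000.

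The strongest regions lost at 24 h were among the strongest of all 0 h regions, with mean percentiles of 99.3 to 99.9. The first, 4:29277801-29278247, had a fold of 24.1 in one 0 h library and 21.2 in the other. It was followed by 18:70856833-70857619 with 19.1 and 20.7, 13:85947403-85947835 with 20.03 and 18.8, 2:162701367-162701936 with 19.9 and 18.3, and 5:15798193-15798504 with 16.4 and 22.2. At 1 h, 3 of these 5 still had a peak in both libraries and 2 in 1 library. The strongest gained region, 1:83190095-83190700, had folds of 16.4 and 13.5 at 24 h, a mean percentile of 96.0. X:107602015-107602574 had 12.3 and 12.6, 2:151764876-151765503 had 10.97 and 15.1, 13:106216544-106216894 had 13.5 and 11.2, and X:122744885-122745260 had 10.6 and 14.3. Of these gained regions, 4 had a peak in both 1 h libraries and 1 in a single 1 h library. Counts rose when a library was left out: the strong lost regions became 3790 without 0h replicate 2 and 3417 without 24h replicate 2, and the strong gained ones 619 to 798 without any 1 of the 4 libraries. Over all peaks, losses and gains were nearly equal without 24h replicate 1, with 16586 lost and 16336 gained. A gain then needed a peak in 1 library and a loss in 2. The losses and gains were 24828 and 8748 without 0h replicate 1, 22746 and 8708 without 0h replicate 2, and 20586 and 10435 without 24h replicate 2.

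**Figure D2:**
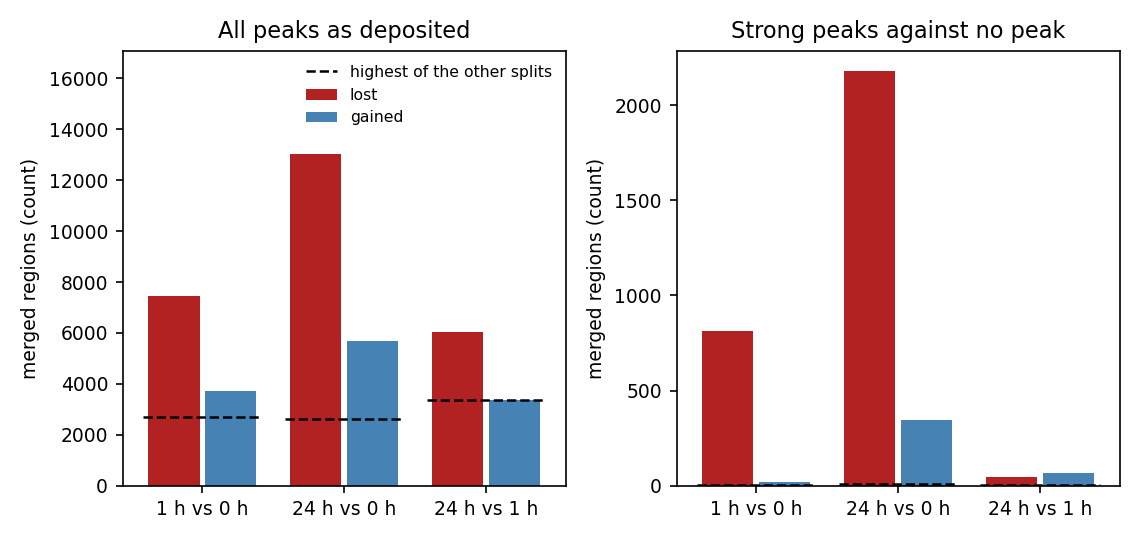
Bars give the number of merged regions lost (red) or gained (blue) in each comparison, for all deposited peaks (left) and for strong peaks against no peak (right); dashed lines mark the highest count from the other splits of the same 4 libraries, which in the right panel are 4, 8 and 2. Lost regions exceed gained ones against 0 h in both panels (815 and 17 at 1 h, 2177 and 343 at 24 h for strong peaks). For all peaks, draws that kept library totals gave such an excess too (4462 and 2405 at 1 h, 7338 and 2180 at 24 h). The other splits mix the times on each side, so they do not carry the depth difference between times.

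The losses at both times overlapped. Of the 815 strong regions lost at 1 h, 753 (92.4%) also had no peak in either 24 h library, and 11 had one in both. Over all peaks, 5901 of the 7438 regions lost at 1 h were lost at 24 h too, against 973 for independent lists and 2221 ± 42 in draws of unchanged libraries against the same 0 h libraries. Of the gained regions, 1522 of 3704 (41.1%) were shared, against 637 for independent lists and 388 ± 19 in the draws, and among strong ones 14 of 17 (82.4%). With a different 0 h library for each comparison, the shared regions are the same by definition but come from longer lists. The 753 were then 44.9% of 1678 or 61.8% of 1218 strong losses at 1 h, and the 5901 were 37.6% of 15698 or 32.6% of 18120 over all peaks. For gains, the 14 were 17.1% of 82 or 13.9% of 101, and the 1522 were 21.4% of 7108 or 20.2% of 7521. These shares had to fall, since the lists grew around the same shared regions. They do not measure what the shared controls add. Part of the higher shares above may still come from the shared controls, and for strong regions no draws were made.

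Other strong 0 h regions still had a peak at 1 h and none at 24 h, a comparison chosen after the data were examined. Of the 2177 strong regions lost at 24 h, 753 had no peak at 1 h, 546 had a peak in 1 of the 1 h libraries and 878 in both. Of these 878, 30 (3.42%) were strong in both 1 h libraries and 728 (82.9%) were strong in neither, so most were already below the strong limit at 1 h. Among 0 h strong regions with a peak in both 1 h and both 24 h libraries, matched on chromosome and 0 h strength, 86.3% ± 1.09 were strong in both 1 h libraries (SD over 1000 draws, lowest 82.8%). Of the 343 strong regions gained at 24 h, 207 (60.3%) already had a peak in both 1 h libraries and 51 (14.9%) in neither.

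Between 1 h and 24 h, few strong regions came or went: 45 regions strong at 1 h had no peak at 24 h, and 69 strong at 24 h had none at 1 h, against 0 to 2 in the other splits. Over all peaks, 6055 regions were lost and 3355 gained. The latter did not exceed the other splits, which gave 1282 to 3358, while the draws gave 4206 ± 61 and 1889 ± 38. The direction differed between the definitions, with more losses over all peaks and more gains among strong ones, and with a −log10 q of at least 5 for presence it was 1281 lost and 1114 gained. The 5 strongest lost regions, led by 22:46865459-46865912 with folds of 9.17 and 9.97 at 1 h, all had a peak in both 0 h libraries. The others were 2:61273023-61273533, 11:15331179-15331610, 18:24268199-24268544 and 6:48884173-48885217, with mean folds of 9.41, 9.85, 8.78 and 8.64. Of the 5 strongest gained regions, 5:126632111-126632386 had a peak in both 0 h libraries. The other 4 had none, namely 13:43260446-43260707, 17:61289391-61289748, 6:76100934-76101369 and 13:73011673-73012180, with mean folds at 24 h of 11.1, 10.9, 10.8 and 10.1. Both directions also turned when single libraries were left out, although losses and gains then had to meet unequal conditions. Strong losses and gains were 266 and 143 without 1h replicate 1, 184 and 233 without 1h replicate 2, 132 and 277 without 24h replicate 1, and 280 and 255 without 24h replicate 2. Over all peaks they were 16428 and 5753, 14678 and 6868, 9395 and 13575, and 13125 and 7977 in the same order. Among the top 40000 peaks in lists of one length they were 2 and 9.

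Lost regions were narrow and weak compared with kept ones in the same earlier libraries. Regions lost at 24 h had a median peak width of 278 and 203 bp in the 0 h libraries, and regions kept in all 4 libraries 501 and 385 bp. Their median folds were 4.96 and 5.22 against 7.83 and 8.73. Regions gained at 24 h were read in the 24 h libraries, where their median within-list percentiles of fold were 31.2 and 33.9. Their widths and folds were not set against those of kept regions, which were read at 0 h. From step 2 on, loss became rarer with strength at 0 h, yet it reached the strongest step when regions were sorted into steps of 10 percentiles of fold, step 10 holding the strongest. In step 2, 31.7% of regions were lost at 24 h and 22.1% at 1 h, in step 7 7.07% and 2.92%, and in step 10 1.94% (216 of 11131) and 0.458% (51 regions). The highest of the other splits of the same libraries reached 15.9% and 15.4% in step 2 at 24 h and 1 h, gave 76 and 39 regions in step 6, 9 and 7 in step 7 and 0 and 1 in step 8, and 0 in steps 9 and 10.

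**Figure D3:**
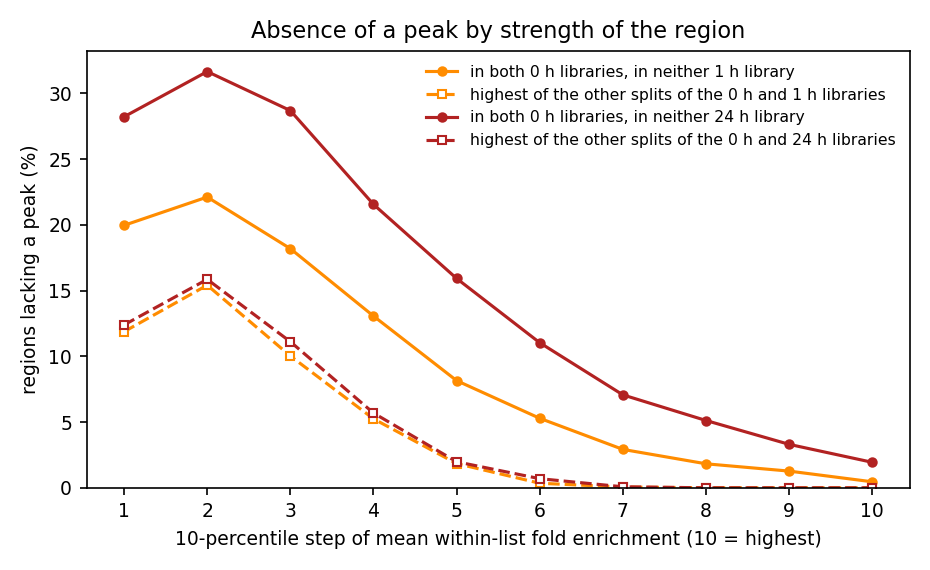
The x axis gives steps of 10 percentiles of the mean within-list percentile of fold enrichment, the y axis the percent of regions in each step that lack a peak; filled circles are 0 h regions absent from both 1 h (orange) or both 24 h (red) libraries, and open squares are the highest percent that the other splits of the same 4 libraries give in that step. At 24 h the loss falls from 31.7% in step 2 to 1.94% in step 10, while the highest of the other splits falls from 15.9% in step 2 to 0 from step 8 on. These splits mix the times on each side and do not carry the depth difference between times.

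Chromosomes differed in how many of their 0 h regions were lost, a comparison chosen after the data were examined. At 24 h, 6.94% of the strong regions of chromosome 13 and 6.14% of those of chromosome 4 were lost, against 1.02% on chromosome 19, 1.51% on chromosome 16 and 1.73% on chromosome 17. At 1 h the shares were 2.91% and 2.71% on chromosomes 13 and 4, and 0.325% on chromosome 19. Over the 23 chromosomes, the share of strong regions lost at 24 h went down with the number of protein-coding genes per Mb (Spearman's rho = −0.75, permutation p = 7e-05, adjusted 8.4e-05 over 6 relations; Pearson's r = −0.76, permutation p = 1e-05, the smallest the permutations can give). Without chromosomes 19 and 17, which are farthest from the median gene density, r was −0.80 and rho −0.68. The share of 24 h regions that were gained went down with gene density as well (rho = −0.72, permutation p = 0.00015, adjusted 0.00015; r = −0.75, permutation p = 2e-05, and −0.65 without those chromosomes), so the relation is not one of losses alone. Chromosomes are not independent replicates, and the relation describes these libraries.

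**Figure D4:**
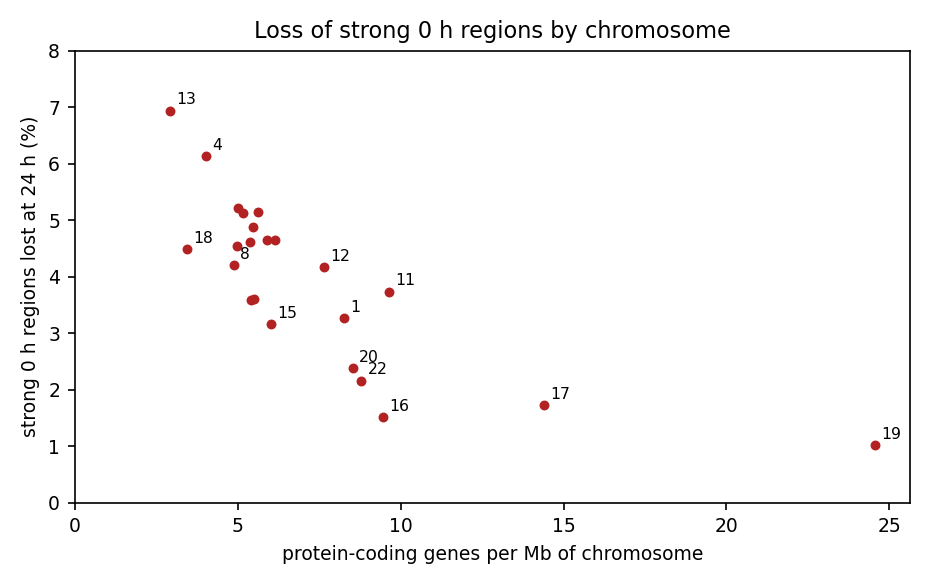
Each point is a chromosome (some are labelled); the x axis is protein-coding genes per Mb and the y axis the percent of strong 0 h regions without a peak in either 24 h library. Chromosome 13 (6.94%) and chromosome 19 (1.02%) mark the ends.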

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

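The −log10 q minimums of 15 and 20, the minimum of 5 for strong peaks, the limit of 10 for all lists, the top-ranked counts, the replicate block, the split of the 0 h libraries between comparisons, and the summit windows and omission of each library for strong counts were tried after seeing the data. The 6 counts over all peaks stayed within 1.5 times with a −log10 q of at least 5, lists of one length, 500 bp summit windows or all chromosomes, and so did the overlaps of losses and of gains between the later times under the first 2 of these; with a different 0 h library for each comparison the overlaps are the same by definition. Where peaks had to cover 50% of a region, gains at 1 h rose to 6900 and losses from 1 h to 24 h to 10894. With only peaks of −log10 q of at least 10, gains fell to 1788 (1 h) and 2980 (24 h), and between 1 h and 24 h losses were 3528 and gains 1609. The remaining counts are losses and gains for 1 h against 0 h, 24 h against 0 h and 24 h against 1 h, in that order. Strong peaks against no peak gave 815 and 17, 2177 and 343, and 45 and 69; with a minimum of 5, 3210 and 694, 6557 and 2534, and 1281 and 1114; with 15, 331 and 2, 1022 and 66, and 2 and 5; with 20, 129 and 0, 494 and 11, and 0 and 0. In lists of one length, the top 20000 peaks gave 20 and 0, 101 and 1, and 0 and 0. The top 30000 gave 95 and 0, 357 and 42, and 0 and 1, the top 40000 254 and 5, 781 and 167, and 2 and 9, and the top 60000 951 and 108, 2236 and 1039, and 105 and 217. Losses exceeded gains against 0 h in each of these, by a ratio that shrank as weaker peaks were let in. For strong regions, summit windows gave 88 gains at 1 h, and 97 losses and 210 gains from 1 h to 24 h. Leaving out each library in turn asks less of a region, and asks it unequally of losses and gains. Losses over all peaks then ranged from 11235 to 18120, 16586 to 24828 and 9395 to 16428. Gains ranged from 7108 to 12623, 8708 to 16336 and 5753 to 13575. Strong losses ranged from 1206 to 1678, 2681 to 3790 and 132 to 280, and strong gains from 71 to 177, 619 to 798 and 143 to 277. All 30 calls of named regions held under the 6 alternatives set beforehand that use every library, and 22 did among the top 40000 peaks. These regions were picked as the strongest calls, with a −log10 q of at least 10 in both libraries that hold them. A minimum of 5, strong peaks against no peak, lists of one length and all chromosomes could therefore hardly change them. The summit windows and the 50% cover were the more open checks. With the replicate number as a block, the exact two-sided permutation p for peaks per library was 0.5 in each of the 3 comparisons, the smallest that 2 pairs can give, and both pairs held fewer peaks at the later time. Replicate 2 held more peaks than replicate 1 at each time, but the labels do not say what the numbers share. Within numbers, 9.24% and 6.09% of the strong regions of a 0 h library had no peak at 24 h, and 4.15% and 3.08% none at 1 h. The alternatives for motifs (the replicate block among them), promoters and gene lists were not run, since no hg19 sequence or annotation was used here.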

Other observations

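The tests of list length, of 0 h strength and repeatability across chromosomes, and of complete loss of whole 1 Mb windows were chosen after the values they use had been seen; the others were set before their values were seen, though for patterns already noticed.

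More strong regions were lost than gained at 24 h, 2177 against 343, while the 24 h lists were shorter and shallower. In lists of one length the top 40000 peaks gave 4.68 times as many losses as gains (2.58 to 5.39 without each library in turn), and the ratio was 2.15 among the top 60000 and 8.50 among the top 30000; all 4 ranks tried were seen before 40000 was taken. Without 0h replicate 2, whose fragment length was the shortest (111 bp), the ratio for strong regions was 6.12 (3790 losses and 619 gains). Leaving out a library asks unequally of losses and gains, here and in the range above, so this ratio cannot decide about fragment length. In single pairs without that library, 9.24% and 7.34% of the strong regions of 0h replicate 1, the deepest library, lacked a peak in the 24 h libraries. In reverse it was 2.49% and 2.61%. The second library had 0.701 and 0.674 of the depth of the first, and 1.43 and 1.48 times it in reverse, so depth may add to this difference. Lower depth is argued against at 1 h, since 1839 strong regions of 0h replicate 2 had no peak in the deeper 1h replicate 2 and such counts were 95 to 388 between replicates, and 0h replicate 1 missed 262 in 0h replicate 2 and 2648 in 1h replicate 1 at nearly the same relative depth (0.789 and 0.779 of its own). Loss of open chromatin after FOXA1 degradation stays as a hypothesis for strong regions, with no untreated 24 h library here to separate it from time in culture. Each 24 h library was shallower than both 0 h libraries, so no pair with a deeper 24 h library exists. At relative depths of 0.889 and 0.855, 0h replicate 2 missed 4734 and 3643 strong regions in the 24 h libraries. That is more than the 262 above at 0.789, but the latter is 1 pair of replicates. Depth at 24 h therefore stays open, and fragment length was left undecided. Differences between libraries other than list length, depth and fragment length were not examined. The excess over all peaks stays open. Draws that kept library totals gave 7338 lost and 2180 gained regions at 24 h, and 4462 and 2405 at 1 h. Unequal list lengths alone thus give more losses than gains. Observed losses and gains were 1.77 and 2.61 times the drawn ones at 24 h, and 1.67 and 1.54 times at 1 h. The draws absorb part of a real change. Lists of one length nearly force losses and gains to be equal (9067 and 7732). Neither can decide.

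Gene-rich chromosomes lost a smaller share of their 0 h regions, and gained a smaller share of their 24 h regions (rho = −0.72). Weaker 0 h peaks on gene-poor chromosomes do not account for all of it: over all regions Spearman's rho was −0.86 over the 23 chromosomes, and −0.80 with the number expected from 0 h strength divided out. Uneven repeatability of peak calls is a candidate explanation over all regions, since the share that split along or across replicate numbers showed the relation as well (rho = −0.87). Uneven repeatability between replicates is argued against for strong regions (rho = −0.75), of which 13 split in those ways against 2177 lost. These splits balance depth between times. They do not show whether the shallower 24 h libraries missed more peaks on gene-poor chromosomes. The shares of strong regions were not corrected for 0 h strength either. A position away from promoters, which are dense on gene-rich chromosomes, was not tested.

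Strong lost regions lay near each other. The extreme case was chromosome 8 from 85 to 86 Mb, where 9 of 18 strong 0 h regions were lost at 24 h and 7 at 1 h. It had the most strong losses of 2201 windows of 1 Mb with at least 20 regions at 0 h, and the next had 6. Of all strong lost regions 14.9% had another within 50 kb, above the 11.3% ± 0.928 (SD, highest 14.2%) of 1000 draws matched on chromosome and 0 h strength, a one-sided permutation p of 0.001 and the smallest these draws can give. Complete loss is argued against only for stretches that span a whole 1 Mb window with at least 20 regions at 0 h, none of which lost more than 61.9% of them; shorter stretches stay open, since 8.41% of strong lost regions had another within 50 kb with a kept region between them, within the range of matched draws though above most of them (mean 7.05%, highest 9.74%, one-sided permutation p = 0.042), and so does loss of some copies. Strong gained regions also lay near strong lost ones, 12.2% within 50 kb against 8.30% ± 1.49 (highest 13.4%) in matched draws of kept regions (two-sided permutation p = 0.024), and 6.54% ± 1.28 once the number of strong 0 h regions within 50 kb was matched too (permutation p = 0.002). That accessibility may move to sites near the lost ones is an undecided hypothesis, since a shared preference of both kinds of region for gene-poor stretches would give the same excess; draws matched on local gene density in hg19 could separate these and were not run.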
